A study of Araneus ventricosus with 24 samples.

How the data were processed

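The samples are RNA from the ampullate gland and the cerebral ganglia of *Araneus ventricosus*, untreated or exposed for 30 days to cadmium, lead or cadmium plus lead, in labelled triplicate (8 groups of 3). Per the labels, RNA was purified with RNeasy Mini Plus columns, libraries were made with a SMARTER mRNA-Seq kit and sequenced on an Illumina NovaSeq. Doses are not given. No genome was used: values are given per assembled gene cluster, with the closest hits in protein and nucleotide databases. The assembler, aligner and counting tool are not given in the sources used here.

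The authors deposited one table of estimated read counts (expected counts) and one of FPKM for the same 142219 clusters and 24 columns. The FPKM unit is not named in the header and was read from the values, which follow the deposited counts scaled by length and library total. Cluster lengths run from 301 to 30353 bases (median 488), 29569 clusters carry an informative description, and these hold 69.8% of counts. Library totals run from 14834065 to 20954478. Only the counts were tested, rounded to whole numbers. The FPKM values served for one measure: length minus the effective length they imply, taken as the mean fragment length, over clusters with over 200 counts, with 15 bases as the tolerance.

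Columns were compared within groups. In the combined gland and combined ganglia replicates 1 and 3, in the lead gland replicates 1 and 3, and in the lead ganglia replicates 2 and 3, held equal counts in every cluster. One of each pair was left out, so 10 distinct libraries per tissue were used. The design fixed earlier assumed 24. Nothing in the labels says that libraries come from separate animals, so p-values measure the spread between libraries.

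Each tissue was fitted once with edgeR 4.0.16 (filterByExpr, TMM, glmQLFit with robust estimation, one mean per group, glmQLFTest) in R 4.3.3, and all 20 libraries once for the difference between untreated tissues and for the exposure by tissue test with 3 degrees of freedom. The groups share one estimate of spread, so groups of 2 libraries are assumed to vary like the others. P-values were adjusted by Benjamini-Hochberg within a comparison and calls are at an adjusted p under 0.05. The departure of the combined change from the sum of the cadmium and lead changes was tested as a contrast. Counts at an unadjusted p under 0.05 are also given. They are no calls, since with no change a share of about 0.05 of the clusters tested is expected there. In the gland the counts for cadmium against untreated, combined against lead and this departure lie below that share.

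Gene lists (silk, metal handling, antioxidant and detoxification enzymes, protein synthesis and turnover, energy and lipid metabolism, nerve signalling, and markers of other tissues) were fixed as patterns on descriptions before the data were examined. So were the comparisons, the tests of clusters and lists, the alternatives not described below as added, and the rule for named genes. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated one, both adjusted over lists. Members were also counted with p adjusted over the list alone. These list tests ask whether members moved more than other clusters. The plan also held fry, a self-contained test that looks at the members alone. It was run, but its results are not given here. Silk clusters were grouped by gland type, bacterial genera chosen and clusters of other organisms selected (a nucleotide hit scoring at least 0.5 per base of the cluster) after the data were seen.

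Named genes follow a rule. For each comparison with untreated they are the 10 largest changes up and the 10 down among calls with a mean of at least 1 CPM, all exposed libraries on one side of all untreated ones and an informative description. Up to 4 called members of each list were added, with 3 spidroins, 2 metallothioneins and 2 members of each marker list by level. Other comparisons name 5 up and 5 down. Calls of other organisms' sequence and clusters high in 1 library were left unnamed or described as such.

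Shares of counts per list and silk type were compared by exact permutation, two-sided. Libraries with lead were compared with those without by exact permutation within cadmium status (100 arrangements). The plan fixed earlier held no test of shares and no pooling of libraries by lead. Changes of 2 exposures were correlated across clusters and set beside 6 simulated data sets with unchanged groups and shared untreated libraries.

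Alternatives were RLE size factors, TMMwsp, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, a fold-change minimum, DESeq2 1.42.0, a fit of only the groups compared, and leaving out each library in turn. Added after the data were seen were all 24 columns counted as libraries, each library's trend along cluster length removed, and the gland without silk clusters. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 made the tables and figures. The fits were tested on simulated data with 50 clusters changed at each of 4 sizes: 17 of 50 clusters with a 64-fold change were recovered for combined against untreated in the gland, 43 for lead against untreated in the ganglia and 44 for the tissues. A list shifted by 1 log2 unit was recovered in 4 of 4 comparisons tried. The simulated clusters varied independently, so this does not show how the list test behaves where members vary together.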

Results

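Transcripts of the ampullate gland, a silk gland, and of the cerebral ganglia of the spider *Araneus ventricosus* were compared between untreated spiders and spiders exposed for 30 days to cadmium, lead or cadmium plus lead. In 4 of the 8 groups, 2 of the 3 deposited columns held the same count in all 142219 clusters. Each such pair was counted once, which leaves 20 distinct libraries. Each tissue then has 3 untreated, 3 cadmium, 2 lead and 2 combined libraries. Changes are log2 ratios ± SE and levels are CPM, which are counts scaled to the library total (with TMM factors for named genes), mean ± SD, in that order of groups where 4 values are given. Gene names are those of the closest described protein, so several clusters can carry one name. Clusters that share a name may be parts of one gene. The preset correlation counts them as nearly independent members, so list p-values with it can be too small.

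In untreated spiders 2 silk types were higher in the gland, and muscle, neuropeptide and cytochrome P450 lists were higher in the ganglia with the preset correlation only. Aciniform spidroins, the proteins of wrapping silk, were higher in the gland for 13 of 14 tested clusters (median log2 difference 9.06, adjusted p = 1.35e-16, and adjusted p = 0.0239 with an estimated correlation). Pyriform spidroins, the proteins of attachment discs, were higher for 4 of 5 (8.04, adjusted p = 1.5e-05, and adjusted p = 0.035 with an estimated correlation). Major ampullate spidroins, the dragline proteins, had a median of 0.23 over 74 clusters (adjusted p = 0.724). The grouping of silk clusters by gland type was made after the data were seen. Tissue names are those of the labels: untreated libraries labelled ampullate gland held 8.19% aciniform and 2.18% pyriform but 0.806% major and 0.0872% minor ampullate spidroin, and untreated ganglia 0.722% major ampullate spidroin. Of 83 muscle clusters, 38 were higher in the ganglia and 1 in the gland (median -3.04, adjusted p = 4.46e-18; 50 and 4 adjusted over the list alone). Of 53 clusters of neuropeptides and their receptors, 25 were higher in the ganglia and 3 in the gland (-3.55, 6.97e-09; 31 and 4). Of 232 cytochrome P450 clusters, enzymes that oxidise lipids and foreign compounds, 68 were higher in the ganglia and 3 in the gland (-1.62, 1e-13; 94 and 9). Clusters of the endoplasmic reticulum and secretion pathway went the other way, with 9 of 41 higher in the gland and 1 in the ganglia (0.64, 7.86e-07; 10 and 1). With an estimated correlation these last 4 lists had adjusted p = 0.396. Arylsulfatase B, a lysosomal enzyme, stood at 95.3 ± 45.7 CPM in the gland and 0.0209 ± 0.0362 in the ganglia (n = 3 each, 11.65 ± 0.80, edgeR adjusted p = 8.05e-06). The acetylcholine receptor subunit acr-16 and rhodopsin 2, a visual pigment, had no reads in the gland and 69.7 ± 5.31 and 110 ± 86.1 CPM in the ganglia. edgeR called 5325 of 51904 clusters, 2031 higher in the gland and 3294 in the ganglia, and DESeq2 called 9530. Without untreated ganglia replicate 1 or 2 the edgeR count was 3359 or 3536.

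Libraries with lead, alone or with cadmium, also differed from all others in sequences that are not the spider's. Clusters of 7 bacterial genera, *Pseudomonas*, *Delftia* and *Acinetobacter* among them, were lower in every library with lead in both tissues. They summed to 0.978 to 18.5 CPM with lead (n = 8) and 39.0 to 280 CPM without (n = 12). In the gland 8 of 24 genera separated the libraries with lead from the others, against at most 4 in any other of the 210 splits, and in the ganglia 10 of 13, against at most 6. *Staphylococcus* was higher with lead in both tissues. Clusters that match rat sequence summed to 1.19 to 43.0 CPM with lead and 0 to 0.659 without, and clusters that match krait snake sequence had no reads in any library with lead and 0 to 22.0 CPM without. The length correction in the FPKM table implies a mean fragment of 278 ± 0.53 bases with lead and 255 ± 9.97 without in the gland (n = 4 and 6), and of 276 ± 4.63 and 256 ± 4.82 in the ganglia. The exact permutation p was 0.01 in each tissue, the smallest that 100 arrangements within cadmium status can give. Within each tissue every library with lead lies on one side of the fragment and of the 7 genera. Across tissues cadmium gland replicate 2, at 273.4 bases, lies above 2 ganglia libraries with lead (271.1 and 272.6), and krait clusters had no reads in cadmium gland replicate 3 either. The labels give no batch or date, so preparation and lead cannot be told apart within a tissue. A single cluster that matches the spider's mitochondrial genome held 12.6% of ganglia counts with lead (11.8 to 13.6%) and 21.7% without (18.2 to 35.4%, the highest in untreated replicate 3; exact permutation p = 0.01), and it enters every share of counts in the ganglia. Cadmium against untreated and combined against lead each compare libraries of one side.

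**Figure D1:**
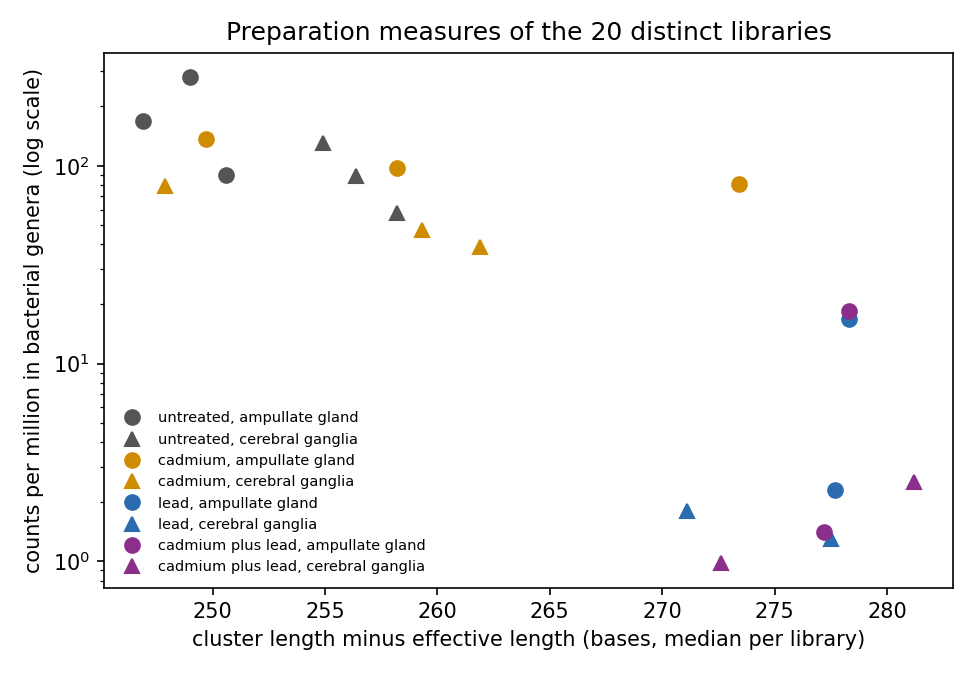
Mean fragment length implied by the deposited FPKM values against the summed CPM of clusters from 7 bacterial genera, for each distinct library. Colours mark the exposure and symbols the tissue.

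With cadmium alone the muscle list of the gland passed downward and the silk list upward with the preset correlation only (adjusted p = 0.1 and 0.994 with an estimated one), while no single cluster passed. Of 56 muscle clusters 12 had a positive change (median -1.13, adjusted p = 5.83e-17, and adjusted p = 0.1 with an estimated correlation), and the share of estimated counts in muscle clusters was 0.427 ± 0.108% against 0.516 ± 0.283% in untreated glands. Of the 2 muscle clusters named by level, titin-like stood at 582 ± 532 and 2248 ± 910 CPM with every cadmium library above every untreated one (1.95 ± 0.94, edgeR adjusted p = 1), and Muscle LIM protein 1 at 956 ± 902 and 257 ± 88.9 CPM (-1.90 ± 0.94, adjusted p = 1). Of 155 silk clusters 105 had a positive change (1.05, adjusted p = 7.67e-07, and adjusted p = 0.994 with an estimated correlation), and 7 rose when adjusted over the list alone. Aggregate spidroins, the proteins of the sticky glue, made up 0.625 ± 0.278% of counts against 0.0709 ± 0.0369%, with every cadmium library above every untreated one (n = 3 each, exact permutation p = 0.1, two-sided, the smallest possible). Of 17 aggregate clusters 10 rose when adjusted over that list alone. Oxidative phosphorylation clusters (-0.27, adjusted p = 3.36e-08) and cytosolic ribosomal proteins (-0.18, 1.56e-05) fell as lists and lipid metabolism rose (0.44, 0.00254), each with adjusted p = 0.994 with an estimated correlation. The most abundant spidroin, an aciniform cluster, stood at 54123 ± 40856 CPM in untreated and 49922 ± 11409 in cadmium glands (-0.12 ± 0.71). edgeR called 0 of 44505 clusters (smallest adjusted p = 0.823), and DESeq2 called 96. At an unadjusted p under 0.05 edgeR had 1273, below a share of 0.05 of the clusters. Other splits of these 6 libraries gave 670 to 3307. In simulated data of this design 25 of 50 clusters with a 64-fold change were recovered and 2 of 50 with a 16-fold change.

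With lead alone the dragline spidroins of the gland were far higher. Major ampullate clusters made up 11.4 ± 2.34% of counts against 0.806 ± 1.19% in untreated glands (n = 2 and 3, exact permutation p = 0.1, the smallest possible). Over both exposures with lead, their share was 10.9% (8.18 to 13.1%, n = 4) against 1.28% (0.113 to 2.35%, n = 6) without (ratio 8.51, exact permutation p = 0.01, adjusted p = 0.0233 over 7 silk types). Neither this pooling by lead nor the silk types were part of the plan fixed earlier. None of the 29 fixed lists passed this test (lowest adjusted p = 0.0967 in the gland and 0.129 in the ganglia), and the fixed silk list had 20.4% (18.5 to 23.8%) against 12.4% (5.88 to 19.2%, adjusted p = 0.132). Passing takes more members at the smallest p (0.01) over 29 lists than over 7 silk types, so the contrast decides nothing. In the ganglia DNA replication and reproductive tissue lists lay above in every library with lead (exact permutation p = 0.01 each). In the gland oxidative phosphorylation (exact permutation p = 0.01), heat shock and ion channels (exact permutation p = 0.02 each) lay below. Conjugation and aminoacyl-tRNA synthetase lists lay above there (exact permutation p = 0.01 each). Tubuliform spidroins, of egg-case silk, also lay above in every library, at 0.0271% (0.00761 to 0.0515%) against 0.000198% (2.3e-05 to 0.000559%, adjusted p = 0.0233). For the other types the ranges overlapped. Aggregate spidroins had 2.52% (0.156 to 7.63%) against 0.348% (0.0338 to 0.926%, adjusted p = 0.0233), a mean carried by the combined libraries: with lead alone they had 0.477 ± 0.453%, below the 0.625% of cadmium alone. Minor ampullate spidroins had 0.925% (0.0260 to 1.68%) against 0.204% (0.00506 to 0.497%) and flagelliform spidroins, of the capture spiral, 0.579% (0.0706 to 1.14%) against 0.0395% (0.00283 to 0.139%), with adjusted p = 0.028 each. Pyriform spidroins had 0.617% (0.0496 to 1.26%) against 2.04% (1.13 to 3.51%, adjusted p = 0.035), and aciniform spidroins 3.42% (0.0662 to 9.85%) against 8.5% (3.75 to 15.5%, adjusted p = 0.09). In the ganglia no silk type passed this test. Of 155 silk clusters 50 rose with lead alone when adjusted over the list alone (median 3.76, adjusted p = 9.19e-23, and adjusted p = 0.373 with an estimated correlation). Muscle fell (14 of 56 adjusted over the list alone, median -2.12, adjusted p = 7.67e-15, and adjusted p = 0.146 with an estimated correlation), and its share was 0.133 ± 0.0519% of counts. Hemolymph and hemocyte clusters fell as a list (-1.25, adjusted p = 0.0088, and adjusted p = 0.805 with an estimated correlation), hemocyanin subunit A among them at 608 ± 653 and 38.4 ± 51.5 CPM (-3.98 ± 1.84, adjusted p = 0.429). edgeR called 0 of 44505 clusters (smallest adjusted p = 0.0575; 5283 at an unadjusted p under 0.05), and DESeq2 called 1848. The edgeR count was 53 without untreated replicate 3, 28 and 12 without combined replicate 1 or 2, and 19 and 12 without lead replicate 1 or 2. RLE size factors move the median of all gland clusters from -0.15 to -0.27 with lead and from 0.07 to -0.03 with cadmium.

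**Figure D2:**
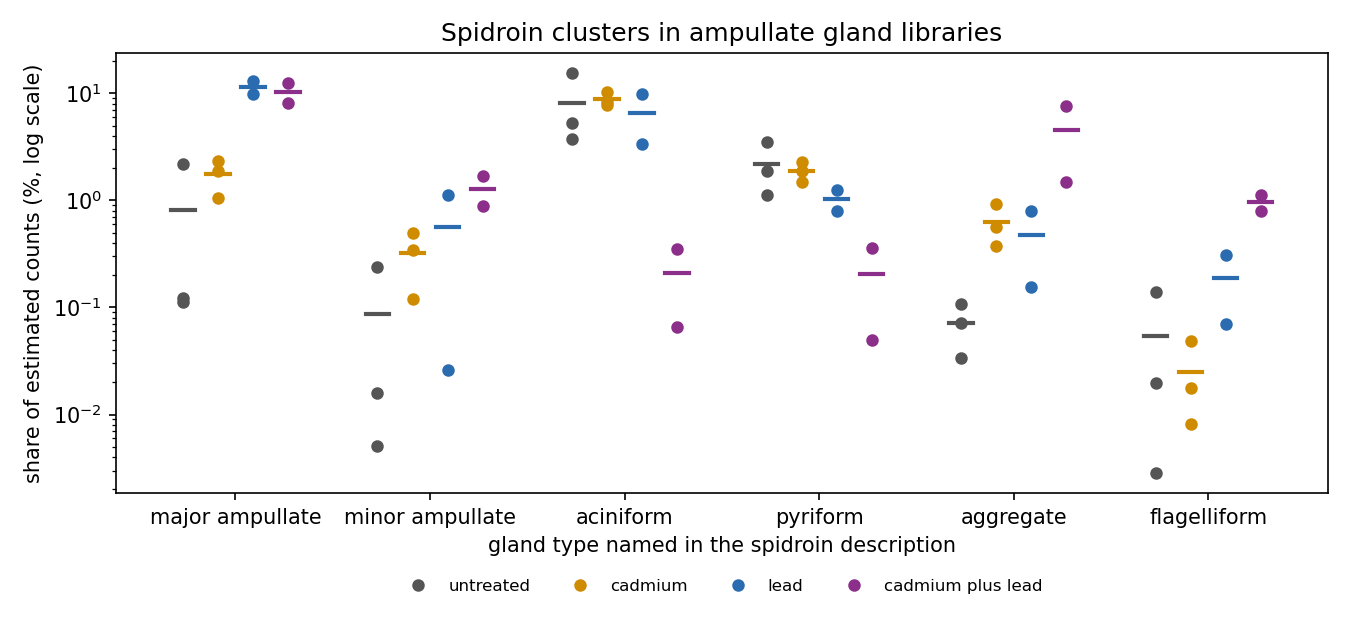
Share of estimated counts, in percent on a log scale, of spidroin clusters named for 6 silk types in the gland. Points are libraries and bars are means of each treatment.

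With cadmium plus lead, some muscle clusters of the gland fell and some clusters of glue and capture silk rose. The muscle and silk lists passed with the preset correlation only (adjusted p = 0.114 and 0.439 with an estimated one). Troponin C, the calcium sensor of muscle, fell by 6.81 ± 0.66 (131 ± 59.3, 40.8 ± 4.91, 8 ± 1.74 and 1.17 ± 0.294 CPM in untreated, cadmium, lead and combined glands, adjusted p = 0.0132). Myosin light chain (-5.73 ± 0.67), myosin heavy chain (-6.05 ± 0.78), Actin-3 (-6.05 ± 0.87) and paramyosin (-6.12 ± 0.93) fell too, and of 56 muscle clusters 7 fell and 27 did so adjusted over the list alone (median -3.20, adjusted p = 1.27e-16, and adjusted p = 0.114 with an estimated correlation). A titin-like cluster of 2147 bases stood at 582 ± 532 and 1654 ± 637 CPM (1.51 ± 1, adjusted p = 0.471), and Muscle LIM protein 1 at 956 ± 902 and 61.3 ± 73.6 CPM (-3.96 ± 1.22, adjusted p = 0.211). Of 155 silk clusters 12 rose, and adjusted over the list alone 64 rose and 9 fell (median 3.92, adjusted p = 5.61e-20, and adjusted p = 0.439 with an estimated correlation). The highest of the rising aggregate spidroin 1 clusters went from 62.8 ± 29.1 to 13239 ± 7675 CPM (7.72 ± 1.04, adjusted p = 0.0388), flagelliform spidroin variant 1 from 2.83 ± 0.524 to 2067 ± 1651 (9.51 ± 1.23) and mesocentin from 4.85 ± 1.60 to 2766 ± 2634 (9.15 ± 0.98). Aciniform spidroins went the other way, with 7 of 14 clusters lower when adjusted over that list alone (median -5.18, adjusted p = 4.62e-10, and adjusted p = 0.0635 with an estimated correlation). The most abundant of them stood at 1062 ± 862 CPM (-5.67 ± 1.04, adjusted p = 0.0705).

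Outside silk and muscle, few combined-exposure calls in the gland fell into the fixed lists. Lipid metabolism rose as a list (2 of 336 clusters, 47 up and 4 down adjusted over the list alone, median 1.03, adjusted p = 3.91e-06, and adjusted p = 0.858 with an estimated correlation), and a fatty acid synthase-like cluster went from 0.0201 ± 0.0349 to 7.37 ± 2.97 CPM (8.11 ± 1.29). D-beta-hydroxybutyrate dehydrogenase, an enzyme of ketone bodies, went from 0.0201 ± 0.0349 to 14.7 ± 4.85 CPM, and was at 30.0 ± 15.8 with lead alone. Cytosolic ribosomal proteins fell as a list (1 of 111, median -0.79, adjusted p = 1.27e-16, and adjusted p = 0.858 with an estimated correlation), with 60s ribosomal protein L44 at 61.4 ± 20.6 and 3.86 ± 1.88 CPM (-3.99 ± 0.61, adjusted p = 0.0443). Oxidative phosphorylation fell as a list over 115 clusters (-0.96, adjusted p = 1.8e-13, and adjusted p = 0.858 with an estimated correlation). Midgut digestion had a median of 0.07, a mean of -0.20 and a downward test (adjusted p = 0.0362, and adjusted p = 0.858 with an estimated correlation), and its median was -0.11 with RLE size factors. The histone methyltransferase SET and MYND domain-containing protein 3 fell from 4695 ± 3846 to 22.1 ± 1.30 CPM (-7.73 ± 1.15), and astakine-like, named for a hemocyte growth factor, from 12.6 ± 4.66 to 0.0382 ± 0.054. edgeR called 100 of 44505 clusters, 53 up and 47 down (6612 at an unadjusted p under 0.05), and DESeq2 called 3271. The count was 0, 28 and 597 without untreated replicate 1, 2 or 3, 23, 11 and 4 without cadmium replicate 1, 2 or 3, 288 and 333 without lead replicate 1 or 2, and 193 and 15 without combined replicate 1 or 2. It was 0 when only untreated and combined libraries were fitted, 26 with the replicate number as a block and 51 without silk clusters.

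Silk types of the gland differed between both metals and lead alone (n = 2 each), a comparison within one side of the preparation measures that does not part the exposure from whole glands of other types in the sample. Aciniform spidroins were lower with both metals than with lead alone (14 clusters, median -5.35, adjusted p = 3.9e-29, and adjusted p = 0.0223 with an estimated correlation), at 0.210 ± 0.203% of counts against 6.62 ± 4.57%. Clusters of one silk type may be parts of few genes, so their number is no count of independent changes. Pyriform spidroins were lower (-2.27, adjusted p = 2.96e-06, and adjusted p = 0.0362 with an estimated correlation), and aggregate (2.72, 1.07e-14, and adjusted p = 0.0285 with an estimated correlation) and flagelliform spidroins (2.18, 1.07e-14, and 0.0362) were higher. When adjusted over that list alone, 9 aciniform clusters were lower. For single clusters edgeR called 0 of 44505 (smallest adjusted p = 0.944; 902 at an unadjusted p under 0.05), DESeq2 161, and without combined replicate 1 or lead replicate 1 edgeR called 9 or 6. Against cadmium alone, silk rose as a list with both metals (23 up and 8 down adjusted over the list alone, median 2.84, adjusted p = 1.02e-18) and muscle fell (20 down and 1 up, -1.95, 1.42e-07), each with adjusted p = 0.447 with an estimated correlation. That comparison crosses the preparation sides. edgeR called 0 clusters in it (5032 at an unadjusted p under 0.05, DESeq2 1857), and 41, 59 and 64 without combined replicate 1, lead replicate 1 or lead replicate 2. The departure of the combined change from the sum of the single changes had 0 edgeR calls (798 at an unadjusted p under 0.05, DESeq2 74), and 6 and 3 without combined replicate 1 or lead replicate 1.

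In the ganglia with cadmium alone, glutathione S-transferase and digestive lists passed downward and the ion channel list upward with the preset correlation only (adjusted p = 0.475, 0.512 and 0.512 with an estimated one), without a call for a single cluster. Their shares of counts cannot decide, as the smallest exact permutation p possible with n = 3 each is 0.1. The exact permutation p was 0.1, 0.4 and 0.2. The glutathione S-transferase share was 0.0540 to 0.0579% with cadmium and 0.0740 to 0.107% in untreated ganglia. Glutathione S-transferases, which conjugate toxic compounds to glutathione, had a positive change in 2 of 34 clusters (median -0.75, adjusted p = 2.29e-09, and adjusted p = 0.475 with an estimated correlation). Voltage-gated ion channels had one in 55 of 69 (0.74, 1.48e-08, and 0.512). Midgut digestion (172 clusters, -0.68, 3.41e-08), hemolymph (60, -0.63, 2.04e-06), oxidative phosphorylation (124, -0.31, 3.28e-08) and cytochrome P450s (210, -0.35, 6.3e-06) fell as lists, and neuropeptides (50, 0.51, 8.84e-06), synapse and transmitter release (105, 0.34, 6.27e-05) and muscle (78, 0.39, 8.84e-06) rose. With an estimated correlation each had adjusted p = 0.512. No cluster passed on its own. Retinal dehydrogenase 1, a marker cluster named by level, stood at 459 ± 71.6 and 271 ± 103 CPM (-0.76 ± 0.35, adjusted p = 0.661). edgeR called 0 of 38659 clusters (smallest adjusted p = 0.248; 2946 at an unadjusted p under 0.05), and DESeq2 called 130. Simulated data of this design recovered 22 of 50 clusters with a 4-fold change and 39 of 50 with a 16-fold change.

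**Figure D3:**
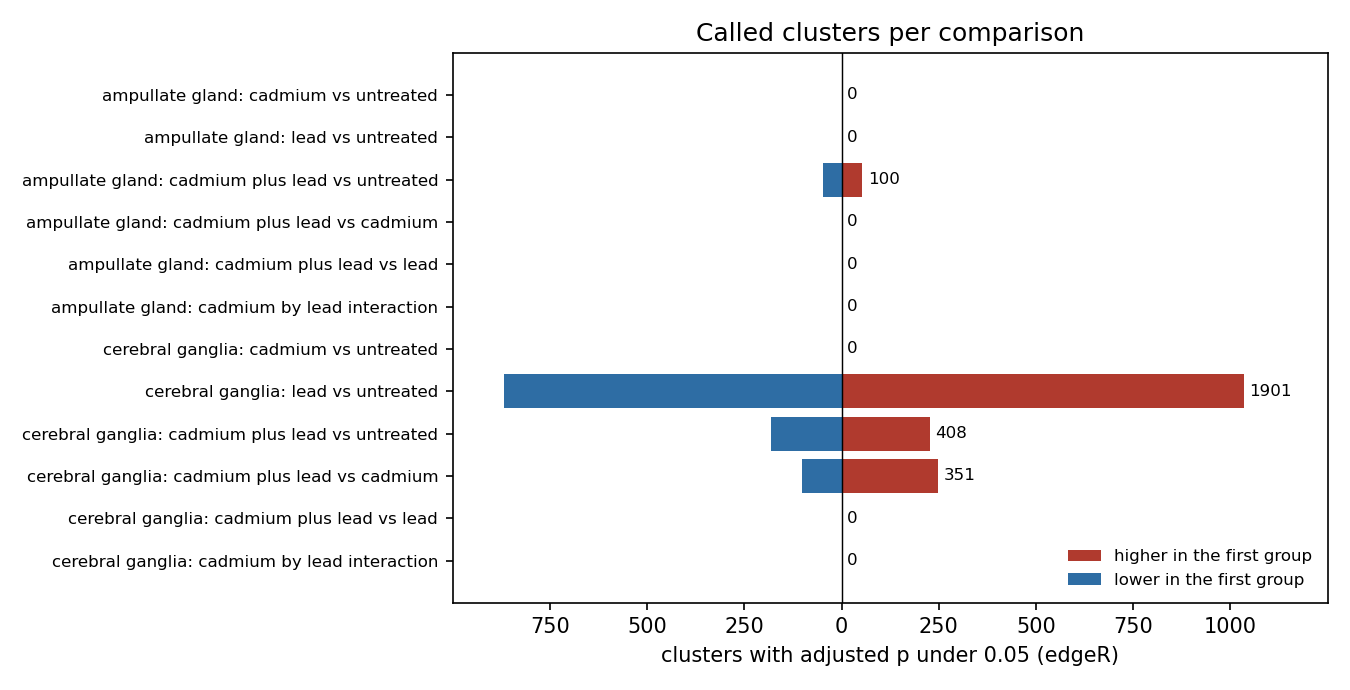
Clusters called at an adjusted p under 0.05 by edgeR in each comparison between exposures, split into higher and lower.

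Lead alone had the most called clusters of the exposures in the ganglia, an order lost when either lead library was left out. The ribosomal and respiratory lists were lower with the preset correlation but not with an estimated one (adjusted p = 0.738). The shares of counts did not pass: ribosomal 2.31 ± 0.303% against 2.94 ± 0.438% (n = 2 and 3, exact permutation p = 0.3) and oxidative phosphorylation 4.11 ± 0.102% against 4.62 ± 1.35% (p = 0.9). 60s ribosomal protein L44 fell from 28.2 ± 1.47 to 1.69 ± 0.191 CPM (-4.06 ± 0.34, n = 3 and 2, edgeR adjusted p = 0.00598), and 40S ribosomal protein S5 from 61.6 ± 6.15 to 8.20 ± 3.10 (-2.91 ± 0.46). Of 103 cytosolic ribosomal proteins 10 fell, 14 adjusted over the list alone, and none rose (median -0.80, adjusted p = 2.57e-15). With an estimated correlation this list and the others of this paragraph had adjusted p = 0.738. Of 124 oxidative phosphorylation clusters 14 fell, cytochrome c oxidase subunits 7C (-2.28 ± 0.41) and 6C (-1.92 ± 0.36) among them, and 4 rose (42 and 12 adjusted over the list alone). This list had a median of -0.76, a mean of 0.11 and a downward test (adjusted p = 5.25e-09). The 4 rising clusters match mitochondrial sequence of rat or sea urchin. Glycolysis and citric acid cycle clusters fell (3 of 47, median -0.77, adjusted p = 1.31e-04), with pyruvate kinase at -1.86 ± 0.44 and cytoplasmic malate dehydrogenase at -1.51 ± 0.37. Glutathione S-transferases fell (4 of 34, -0.66, 0.00123), with glutathione S-transferase Mu 1 at 47.7 ± 9.63 and 7.84 ± 0.57 CPM (-2.60 ± 0.42). Copper/zinc superoxide dismutase, an antioxidant enzyme, fell from 225 ± 58.2 to 64.3 ± 3.37 CPM (-1.80 ± 0.44). Lysozyme 1 (-3.18 ± 0.46), which attacks bacterial walls, kynurenine formamidase (-4.22 ± 0.71) and vitellogenin-like (-4.84 ± 0.93) fell too. Silk clusters fell (4 of 114, median -2.09, adjusted p = 2.89e-06), with the most abundant, major ampullate spidroin 2 variant 5, at 2149 ± 1996 and 160 ± 20.2 CPM (-3.75 ± 1.05, adjusted p = 0.0693).

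Ion channel, synapse and ubiquitin lists passed upward in the same comparison with the preset correlation, and with an estimated one had adjusted p = 0.738. Of 69 clusters in the voltage-gated ion channel list 7 rose and none fell (15 up and 4 down adjusted over the list alone, median 1.22, adjusted p = 2.04e-07). Among them were the potassium channels Shal-like (2.83 ± 0.49) and the small conductance calcium-activated channel (2.11 ± 0.39). The latter is in the list by its description, though it is named for activation by calcium. Of 105 clusters of synapse and transmitter release 9 rose (12 up and 1 down adjusted over the list alone, 0.46, 2.15e-04), among them rab3 GTPase-activating protein (2.36 ± 0.31), syntaxin-binding protein 5 (2.50 ± 0.42) and synaptotagmin-7-like (2.36 ± 0.46). Of 152 neurotransmitter receptors and enzymes 8 rose, with 5-hydroxytryptamine receptor 2A-like at 3.24 ± 0.55, and 6 fell, with acetylcholine receptor acr-16 from 38.7 ± 1.98 to 6.38 ± 2.43 CPM (-2.60 ± 0.31; list adjusted p = 0.0847). Of 355 proteasome and ubiquitin clusters 31 rose and 3 fell (56 and 10 adjusted over the list alone, median 0.16, mean -0.24, upward test, adjusted p = 0.00923), with the ligases HERC2-like at 3.06 ± 0.41 and UBR3 at 1.84 ± 0.29. Lipid metabolism had 14 up and 11 down of 299 (adjusted p = 0.7), with fatty acid synthase at 3.05 ± 0.41 and calcium-independent phospholipase A2-gamma at 3.46 ± 0.46. Of its falling calls 1 matches krait snake sequence. Cytochrome P450s had 6 up and 5 down of 210 (adjusted p = 0.104). edgeR called 1901 of 38659 clusters, 1034 up and 867 down (9614 at an unadjusted p under 0.05), and DESeq2 called 5348. The count was 1186, 925 and 200 without untreated replicate 1, 2 or 3, 1031 without cadmium replicate 2, and 5 and 0 without lead replicate 1 or 2. It was 65 when only untreated and lead libraries were fitted and 728 with the replicate number as a block.

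**Figure D4:**
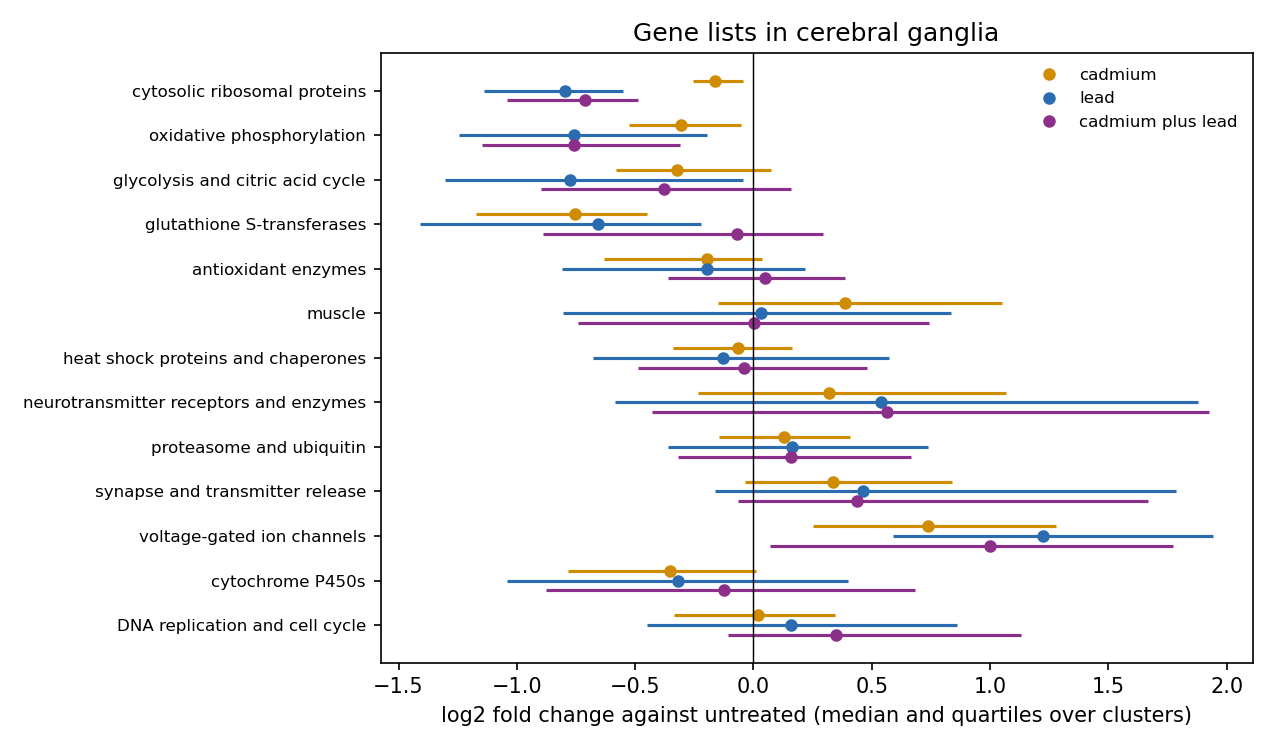
Median and quartiles of the log2 change of 13 lists in the ganglia for each exposure against untreated. The black vertical line marks no change.

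With cadmium plus lead the ganglia had fewer calls than with lead alone when all libraries were used. A cytochrome P450 of hormone synthesis and a cuticle protein were higher. Cytochrome P450 315a1, an enzyme of ecdysteroid synthesis, stood at 1.69 ± 0.622, 2.63 ± 0.694, 4.12 ± 1.98 and 26.0 ± 8.14 CPM (3.93 ± 0.45, adjusted p = 0.0157), and of 210 P450 clusters 6 rose and none fell (list adjusted p = 0.796). Cuticle protein 10.9 went from 11.2 ± 7.52 to 153 ± 33.6 CPM (3.77 ± 0.64), and of 59 cuticle clusters 2 rose and 1 fell (25 and 3 adjusted over the list alone, median 2.93, adjusted p = 0.0136, and adjusted p = 0.782 with an estimated correlation). Most of the cuticle rise lies in 1 library: the share was 0.0288 and 1.47% in combined replicates 1 and 2, against 0.0188 to 0.0236% in untreated ganglia. Ribosomal proteins fell (3 of 103, -0.71, 1.88e-15), L44 to 2.54 ± 0.687 CPM (-3.47 ± 0.33, adjusted p = 0.0083), and so did oxidative phosphorylation (3 of 124, 34 down and 11 up adjusted over the list alone, -0.76, 5.06e-11), both with adjusted p = 0.714 with an estimated correlation. The 3 respiratory clusters that rose match human or rat mitochondria. Ion channels (57 of 69 with a positive change, 1, 1.17e-04), synapse and transmitter release (1 of 105 called, 0.44, 3.12e-04), venom and toxin-like clusters (0.88, 2.35e-04) and midgut digestion (0.74, 8.97e-04) rose as lists, all with adjusted p = 0.714 with an estimated correlation. The zinc finger protein AEBP2 fell from 61.1 ± 25.5 to 5.10 ± 0.315 CPM (-3.58 ± 0.54) and kielin/chordin-like protein, an extracellular protein, from 2849 ± 1948 to 352 ± 67.4 (-3.02 ± 0.60). edgeR called 408 of 38659 clusters, 227 up and 181 down (8554 at an unadjusted p under 0.05), and DESeq2 called 3880. The count was 14 and 34 without untreated replicate 1 or 3, 151, 99 and 104 without cadmium replicate 1, 2 or 3, 96 and 87 without lead replicate 1 or 2, and 18 without combined replicate 2. It was 0 when only untreated and combined libraries were fitted and 43 with the replicate number as a block.

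With both metals against cadmium alone, lipid, digestive and cuticle lists of the ganglia passed upward with the preset correlation but not with an estimated one (adjusted p = 0.474, 0.474 and 0.57), a comparison that crosses the preparation sides and in which combined replicate 2 again carries most of the cuticle share. Lipid metabolism rose (14 of 299, median 0.60, adjusted p = 2.24e-06), as did midgut digestion (6 of 172, 1.28, 3.65e-12), venom and toxin-like clusters (3 of 145, 1.30, 3.65e-12), cytochrome P450s (10 of 210, 0.33, 0.0166) and cuticle (4 of 59, 32 adjusted over the list alone, 3.32, 2.3e-06). Ribosomal proteins fell (2 of 103, -0.59, 2.11e-10). With an estimated correlation their adjusted p ranged from 0.474 to 0.764. L44 fell by 3.64 ± 0.33 (adjusted p = 0.00547), AEBP2 by 3.73 ± 0.55 and autism susceptibility gene 2 protein-like by 5.45 ± 0.84, and BTB/POZ domain-containing protein 6-A rose from 0.0192 ± 0.0332 to 4.18 ± 0.634 CPM (7.27 ± 1.18). The rises of bromodomain-containing protein 4 (69.8 ± 95.4 CPM) and of the longest cuticle protein 10.9 named here (516 ± 729 CPM) have an SD above the mean. edgeR called 351 clusters, 249 up and 102 down, and DESeq2 2689. The count was 8, 849 and 743 without untreated replicate 1, 2 or 3, 21, 13 and 11 without cadmium replicate 1, 2 or 3, 117 and 131 without lead replicate 1 or 2, 39 without combined replicate 2, and 37 with the replicate number as a block. Against lead alone, silk (2.53, adjusted p = 9.64e-20), cuticle (3.11, 1.53e-07) and midgut digestion (0.63, 1.66e-07) rose as lists, each with adjusted p = 0.755 with an estimated correlation. edgeR called 0 clusters there (2242 at an unadjusted p under 0.05, DESeq2 184), and 151 or 1 without combined replicate 1 or lead replicate 1. The departure from the sum of the single changes had 0 edgeR calls (3920 at an unadjusted p under 0.05, DESeq2 396), and 91 or 1 without the same libraries.

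The lead and combined changes resembled each other more than shared untreated libraries alone gave in simulation. Across 38659 ganglia clusters their log2 changes had r = 0.70 against 0.40 in simulated data with unchanged groups (covariance difference 1.37), and 139 rising and 157 falling calls were shared, where independent lists, which leave out the shared untreated libraries, give 6.07 and 4.06. In the gland r was 0.81 against 0.38 (covariance difference 4.47). Cadmium and lead had 0.37 against 0.43 in the gland (covariance difference 0.185) and 0.55 against 0.45 in the ganglia (0.515), and cadmium and combined 0.39 against 0.43 (0.352) and 0.37 against 0.45 (0.198). In 3 of these 4 pairs r lay below the simulated mean while the covariance lay above the highest simulated one. Clusters are not independent replicates, the 3 untreated libraries cannot be split between exposures, and lead and combined libraries also share the preparation side. Between tissues, over 32863 clusters and with no shared library, r was 0.00493 for cadmium, 0.496 for lead and 0.360 for both. Of the clusters called with both metals in the gland, 2 rising and 9 falling were also called with lead in the ganglia, where independent calls give 1.32 and 0.951. Lead and combined against untreated cross the preparation sides in both tissues, and cadmium against untreated does not. These similarities between tissues therefore cannot tell lead from preparation. A difference in the exposure effect between tissues was called by edgeR for 0 of 51904 clusters (smallest adjusted p = 0.0605; 3185 at an unadjusted p under 0.05), and DESeq2 called 585. Without combined gland replicate 1 edgeR called 78, and without gland lead replicate 2 or combined ganglia replicate 2 it called 5 each. It called 2 without gland lead replicate 1 or either ganglia lead library, and 1 without ganglia cadmium replicate 1, untreated gland replicate 3 or combined ganglia replicate 1.

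Of the metal-handling list, 2 of 41 ganglia clusters were called with lead, and none in the other comparisons with untreated. The main metallothionein cluster, named for a protein that binds cadmium, stood at 2.31 ± 1.49, 6.56 ± 1.80, 7.85 ± 3.89 and 7.95 ± 3.23 CPM in the gland, with every exposed library above every untreated one (log2 changes 1.5 ± 0.62, 1.76 ± 0.67 and 1.78 ± 0.67, edgeR adjusted p = 1, 0.382 and 0.288). In the ganglia it stood at 16 ± 3.20, 13.6 ± 1.65, 25.1 ± 10.8 and 29.0 ± 17.6 CPM (adjusted p = 0.908, 0.338 and 0.236). The other metallothionein cluster named by level is not described here. Metal binding and metal transport passed as a list in no comparison with untreated. In the ganglia with lead, zinc transporter 1, which exports zinc, rose from 1.04 ± 0.481 to 5.95 ± 0.011 CPM (2.51 ± 0.49, adjusted p = 0.0282), and heat shock factor protein 1, the regulator of heat shock genes, from 39.3 ± 4.97 to 92.4 ± 6.18 (1.23 ± 0.27). Heat shock proteins and chaperones had 3 up and 1 down of 89 there (list adjusted p = 0.888). Of 181 clusters of conjugation, esterases and ABC transporters 11 rose and 4 fell (list adjusted p = 0.197), with multidrug resistance-associated protein 1, an export pump, at 2.31 ± 0.40.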

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

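The tests of the lead pattern, of the silk types, of a lower share of muscle and other cells, and of other splits of the libraries were chosen after the results were seen. The 2 tests of transcript length in the ganglia lists were written before their values were seen, though the length trend itself is an added alternative.

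3 shares of counts moved in opposite directions in gland and ganglia, with every exposed library on one side of every untreated library in each tissue. They were picked from a scan of 29 lists, 7 silk types and 1 cluster under 3 exposures. With so few libraries, some such cases can arise by chance. The difference between tissues was not tested. Major ampullate silk with lead had a ratio to untreated of 14.2 in the gland and 0.125 in the ganglia. Voltage-gated ion channels with lead had 0.488 and 1.76, and innate immunity with cadmium plus lead had 1.22 and 0.702.

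The deposited FPKM values, which no comparison uses, hold a signal that separates libraries with lead from those without. The implied mean fragment was longer with lead by 23.2 bases in the gland and by 19.2 bases in the ganglia.

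The calls between libraries with and without lead are the first pattern. A length bias of the libraries is argued against as the whole cause, since 1162 of the 1901 lead calls in the ganglia stayed called in the same direction with the length trend removed. A library batch that coincides with lead has the values it needs: 7 bacterial genera were lower in every library with lead in both tissues. Counting either direction, 8 genera in the gland and 10 in the ganglia separated these libraries, against at most 4 and 6 in other splits. Within a tissue 0 libraries part lead from preparation (across tissues the 273.4 bases of 1 cadmium gland library lie in the range of ganglia with lead), so the 2 cannot be told apart, and the batch may account for any part of these calls.

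The silk types of the gland are the second pattern: dragline spidroins higher in every library with lead, and with both metals glue and capture spidroins highest and attachment and aciniform spidroins lowest. For the dragline part, reads shared among major ampullate clusters are argued against, since their lowest summed share with lead was 3.48 times the highest without. This sum does not address reads shared between silk types, nor the other types of the pattern. Whole glands of other types in the sample may contribute: types moved in opposite directions, with a median of -5.18 for aciniform and 7.70 for aggregate clusters. Major ampullate clusters, however, did not move as a block (interquartile range 4.63), and the test of directions was added once that range was seen. Preparation or animals that coincide with lead stay open too (0 libraries without lead in the fragment range of those with lead), so these, other glands and the exposure cannot be told apart.

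The third pattern is lower ribosomal and respiratory and higher channel and synapse transcripts in the ganglia with lead, lists that pass with the preset correlation only. Transcript length is argued against for both parts: with the length trend removed, the higher of the falling medians was -0.50, and the lower of the rising medians lay 0.33 above that of all clusters. The synapse list was then near the threshold (adjusted p = 0.0495), the ribosomal list far past it (1.44e-11). A lower share of muscle and other cells cannot be told apart from a change within nerve cells, since 1 of the lists of muscle, cuticle and midgut had a median above 0 and the others lay below (0.03, -1.07 and -0.06), while their shares lay above untreated but within its spread or that with lead (5.33 against 5.09%, 0.0237 against 0.0211% and 0.605 against 0.462%). The coinciding preparation stays open here as well and cannot be told apart from lead exposure.

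Other splits of the 6 libraries of a comparison are too few for a share under 0.05. For cadmium against untreated the real split gave 0 calls. That 10 of 10 splits gave at least as many was therefore fixed in advance and decides nothing. The highest other split gave 0 in the gland and 4 in the ganglia. For the untreated tissues 1 of 10 did, the real one, with 5325 calls against 0 for the highest other.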

How the results depend on the processing

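All 24 columns as libraries, removal of the length trend and the gland without silk clusters were alternatives chosen after the results were seen. Counts of calls stand in this order where 14 are given: in gland and then ganglia cadmium, lead and combined against untreated, combined against cadmium, combined against lead and departure from additivity, then the tissue difference and the exposure by tissue test. DESeq2 called 96, 1848, 3271, 1857, 161, 74, 130, 5348, 3880, 2689, 184, 396, 9530 and 585, and edgeR with no filter, which tests more clusters, 254, 1445, 2182, 1528, 113, 59, 570, 4800, 3994, 3094, 661, 1169, 8090 and 1434. All deposited columns, whose copies lower the spread by construction, gave 1361, 2002 and 498 for gland lead, combined and combined against cadmium, 8775, 6507, 4445, 94 and 275 for the ganglia from lead on, and 9153 and 479 for the last pair. A fit of only the groups compared, with fewer libraries, gave 0 for gland combined, 65 and 0 for ganglia lead and combined, and 2302 for the tissues. For gland lead RLE size factors gave 3, TMMwsp 5 and the length trend 6. For the exposure by tissue test RLE and the length trend gave 2 each. The length trend gave 8 for gland combined against cadmium and 266 for ganglia combined. Without silk gland combined had 51. The replicate block gave 26 for gland combined and 728, 43 and 37 for ganglia lead, combined and combined against cadmium. Residuals of libraries with the same number correlated at a mean r of -0.0328 in the gland and 0.038 in the ganglia, so no pairing was assumed. The cause of the other shifts was not tested. A filter of 1 CPM in 3 libraries and a log2 minimum of 1 left every count on its side, the largest shift being 408 to 584 for ganglia combined with the filter. Leaving out 1 library at a time gave, in the same order, 0 to 0, 0 to 53, 0 to 597, 0 to 64, 0 to 9, 0 to 6, 0 to 0, 0 to 1957, 14 to 413, 8 to 849, 0 to 151, 0 to 91, 3359 to 7263 and 0 to 78. A group left with 1 library is assumed to vary like the others. Of 348 list tests 147 passed, 144 with RLE, 136 with the block, 146 with the length trend and 0 with an estimated correlation. These are the fixed lists in the 12 comparisons of exposures, without the silk types and the tissue comparison, where some passed with an estimated correlation. RLE turned the gland median of secretion with cadmium from 0.01 to -0.13, and the block turned that of cuticle with both metals from -0.36 to 0.47. For named clusters, 4812 values under alternatives gave 3448 on the same side, 1194 no longer past the threshold, 22 newly past it, 148 that changed sign where the cluster was not called to begin with, and 0 reversals of a called cluster. The limma alternative for values that are not counts did not apply, as the files hold counts. Interactions have no fit of only the groups compared, and the exposure by tissue test has no log2 minimum. Simulation recovered 9 of 50 clusters with a 4-fold change for ganglia lead and 0 for gland combined.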

Other observations

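The reads of other organisms were looked at after the results were seen.

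Libraries hold sequence of other organisms, and part of it follows lead. Lead gland replicate 1 and combined gland replicate 2, both with lead, had 674 and 1114 CPM in *Sphingomonas* and *Ralstonia* clusters, and untreated gland replicate 1 had 75.6 CPM in *Corynebacterium* clusters. Clusters that match human sequence summed to 13.7 to 172 CPM with lead and 16.5 to 265 CPM without, and those that match sea urchin to 9.51 to 31.8 and 12.1 to 47.5 CPM. Clusters that match a cloning vector summed to 0 to 0.173 CPM in ganglia with lead and 1.16 to 2.91 in the others. In the ganglia with lead, 4 calls up match rat and 2 calls down match krait snake. Both krait clusters are in the venom and toxin-like list, and 1 of them is also in lipid metabolism. Rat clusters reached 32.8 CPM on average in ganglia with lead and 3.41 in glands with lead.

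Silk clusters made up 0.871 ± 0.852% of counts in untreated ganglia (n = 3), 1 ± 0.790% with cadmium (n = 3), 0.142 ± 0.0834% with lead (n = 2) and 0.750 ± 0.203% with both (n = 2), mean ± SD. Muscle clusters made up 5.09 ± 1.73, 6.05 ± 1.18, 5.33 ± 0.440 and 5.38 ± 1.83% in the same groups. Exact permutation tests of each exposed group against untreated gave p of 0.3 to 1 for silk and 0.4 to 0.9 for muscle. The smallest p possible in these tests is 0.1, so none could have passed.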
